A study of Mus musculus with 22 samples.

How the data were processed

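Bulk messenger RNA of 22 mouse libraries was measured by sequencing: 16 from LLC lung carcinoma cells and 6 from B16 melanoma cells, transduced with a polycistronic vector for PU.1, IRF8 and BATF3, or with eGFP as controls. The deposited table holds raw counts per Ensembl gene, whole numbers with a different total in every library, not normalized. The submitters' processing notes name bcl2fastq 2.20, STAR 2.5.3a, DESeq2 1.20 and genome GRCm38.p5, without the counting tool, the annotation release or a design formula. Of 31053 genes in the table, 30934 matched a symbol and 31011 had coordinates in GENCODE M21 on GRCm38. The 119 without a symbol held 0.0405% of all counts, 28 symbols were carried by more than 1 gene, and 8097 genes had no count in any library. Ifi30, Mx2 and Cxcl11, members of the fixed lists, are not in the table.

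Samples were grouped by line and day as the labels give them: LLC control (n = 4), day 3 (n = 4), day 5 (n = 2), day 7 (n = 3) and day 9 (n = 3), and B16 control (n = 2) and day 9 (n = 4). Total counts ranged from 266764 (LLC day 5 replicate 2) to 5669232 (LLC day 3 replicate 1), with the total of each library in the results. Between 11798 and 16401 genes (median 13102) had at least 1 count in a library. A group without counts has an upper limit of 3 counts over its libraries, which is the floor used for lower limits of a fold. For a group with 1 to 3 counts the ratio of pooled CPM is given with a 95% interval (exact, conditional on the sum of both counts).

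Gene tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3: filterByExpr with a minimum count of 10 (11418 genes tested), TMM normalization, estimated dispersions, glmQLFit and glmQLFTest on 1 fit with a mean for each of the 7 groups and no replicate block, with a prior of 9.8 degrees of freedom. Benjamini-Hochberg adjustment was over the genes of a contrast and genes were called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Contrasts were LLC day 3, 5, 7 and 9 and B16 day 9 against the same line's controls, LLC day 9 against day 3, the 3 steps between neighbouring LLC days, B16 against LLC controls, and the day 9 effect in B16 minus that in LLC (interaction). Groups with 2 libraries borrow the spread of the other groups in this fit. CPM values are counts scaled to 1e+06 of the effective library size, the total over tested genes times the TMM factor. Limits and ratios of a fold use the same sizes. List levels are means of log2(CPM + 1).

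The 30 gene lists, the panel of named genes, the tests and their alternatives were fixed before the data were examined. The lists were cDC1 identity, MHC class I and class II presentation, cross-presentation and phagosome, costimulation and maturation, type I interferon and interferon gamma response, Toll-like receptors and adaptors, chemokines and cytokines, pan-leukocyte, macrophage and monocyte, cDC2, pDC, B cell, T and NK cell, neutrophil and mast cell, mesenchymal and extracellular matrix, epithelial, melanocyte, cell cycle G2/M and S phase, p53 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, lysosome, unfolded protein and integrated stress, immediate early and dissociation stress, cytosolic ribosomal proteins and mitochondrially encoded genes. Spi1, Irf8 and Batf3 are in no list. Lists with at least 5 tested members were tested with camera (preset correlation 0.01) and adjusted over the lists of a contrast, with an estimated correlation and fry as alternatives. Counts of list members risen or fallen come from the gene test, adjusted over all genes and over the list alone.

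Genes named in the text are the fixed panel; for each list and contrast up to 3 called members per direction with the largest log2 fold change and at least 1 CPM in the higher group; and for each contrast the 8 called genes per direction with the largest log2 fold change and at least 10 CPM in the higher group. Of the panel, 1 gene was tested with the others and counted in the totals and lists, and is not reported here. The effects at day 9 in both lines were correlated across genes (Pearson and Spearman, jackknife SE over libraries); genes are not independent replicates.

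Alternatives were DESeq2 1.42.0 (Wald test, independent filtering off), limma voom with sample quality weights, RLE in place of TMM, Spi1, Irf8, Batf3 and the mt- genes left out, no low-count filter, a minimum count of 50, only the groups compared, the replicate number as a block, a test against an absolute log2 fold change of 1 (glmTreat), and each replicate left out in turn. A fit without LLC day 5 replicate 2 and LLC control replicate 4 was added after the data were seen. Other splits of the libraries of a contrast were fitted to count how often they gave as many genes or lists.

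The fits were tested on simulated data with the same groups and depths and 67, 67 and 66 genes changed by log2 1, 2 and 4. At these sizes edgeR recovered 13.4, 83.6 and 100% for LLC day 3 against controls, 3.00, 59.7 and 97.0% for LLC day 9, 4.50, 32.8 and 95.5% for LLC day 5, 6.00, 43.3 and 100% for B16 day 9, and 0, 22.4 and 90.9% for the interaction, with 2 to 5 false calls. For LLC day 9 against day 7 edgeR recovered 3.00, 68.7 and 98.5%, with 3 false calls. The changed genes were picked only among those with a mean of at least 10 CPM, so recovery of scarcer genes was not measured. For LLC day 9, DESeq2 made 12 false calls and voom 3. A list shifted by log2 1 was recovered by camera (adjusted p = 1.39e-23) with 0 other lists called. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera calls lists wrongly where genes are correlated, as in the real data. Sample and gene tables were handled with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.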

Results

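Messenger RNA was counted per gene in 22 libraries from LLC, a mouse Lewis lung carcinoma line, and B16, a mouse melanoma line. Cells had received a single vector carrying PU.1 (gene Spi1), IRF8 and BATF3, transcription factors that specify conventional type 1 dendritic cells (cDC1), the cells that present tumour antigen to CD8 T cells. Controls carried eGFP and, per the labels, were unsorted for CD45 and MHC-II, whereas reprogrammed cells were sorted as CD45+ MHC-II+. The protocol also describes eGFP+ CD45+ sorts of LLC at day 7 and day 9. LLC was sampled as controls (n = 4) and at day 3 (n = 4), day 5 (n = 2), day 7 (n = 3) and day 9 (n = 3), and B16 as controls (n = 2) and at day 9 (n = 4). The labels do not say whether replicates are separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

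Total counts were 2120631, 1541175, 1214950 and 1079298 in LLC controls 1 to 4, and 5669232, 1857175, 2792964 and 3727509 at day 3. They were 2975697 and 266764 at day 5, 873191, 1057966 and 1603637 at day 7, and 732517, 1053574 and 1310350 at day 9. B16 controls had 1142901 and 1548744 counts, and B16 day 9 libraries 2909900, 1065265, 1316555 and 1221765. Of 31053 genes in the table, 11418 passed the low-count filter and were tested with edgeR quasi-likelihood F tests, in 1 fit over all 22 libraries and 7 groups. Benjamini-Hochberg adjustment was over the genes of each contrast, with a call at adjusted p below 0.05. Values below are CPM, counts scaled to 1e+06 of the TMM effective library size, with the SD over libraries. Fitted log2 fold changes are given with their SE. Where a group had no counts, the fold is a lower limit set by 3 counts over that group, and for 1 to 3 counts it is a ratio of pooled CPM with a 95% interval. Such limits and intervals cover counting error only.

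The factors and the surface proteins used for sorting come first. Spi1 (ENSMUSG00000002111, chromosome 2: 91082390-91115756, GRCm38, GENCODE M21) went from 1 count in the LLC controls to 587 ± 218 CPM at day 3 (n = 4; ratio 3951, 95% interval 709 to 156070) and 248 ± 45.0 CPM at day 9 (n = 3). Irf8 (ENSMUSG00000041515, chromosome 8: 120736358-120756694) rose by log2 8.94 ± 0.78 at day 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.64e-09). Batf3 (ENSMUSG00000026630, chromosome 1: 191097847-191108945) rose by 7.80 ± 0.72 (adjusted p = 1.41e-08). Together the 3 genes took 0.177 ± 0.0610% of counts at day 3 (n = 4), 0.138% and 0.00337% in day 5 libraries 1 and 2, 0.0886 ± 0.0214% at day 7 (n = 3), 0.0745 ± 0.00960% at day 9 (n = 3) and 0.0280 ± 0.00490% in B16 at day 9 (n = 4). The counts cannot separate vector from endogenous transcripts of these genes. Ptprc (ENSMUSG00000026395, chromosome 1: 138062861-138175708), the gene of CD45, went from 1 count in the LLC controls to 318 ± 69.6 CPM at day 3, and in B16 from 0 counts to 47.4 ± 37.8 CPM at day 9. Ptprc and the class II genes are selected by the sort, so their rise is partly the gate. For other genes too, the factors, selection by the sort and any difference in days of culture cannot be told apart in contrasts with the unsorted controls.

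**Figure D1:**
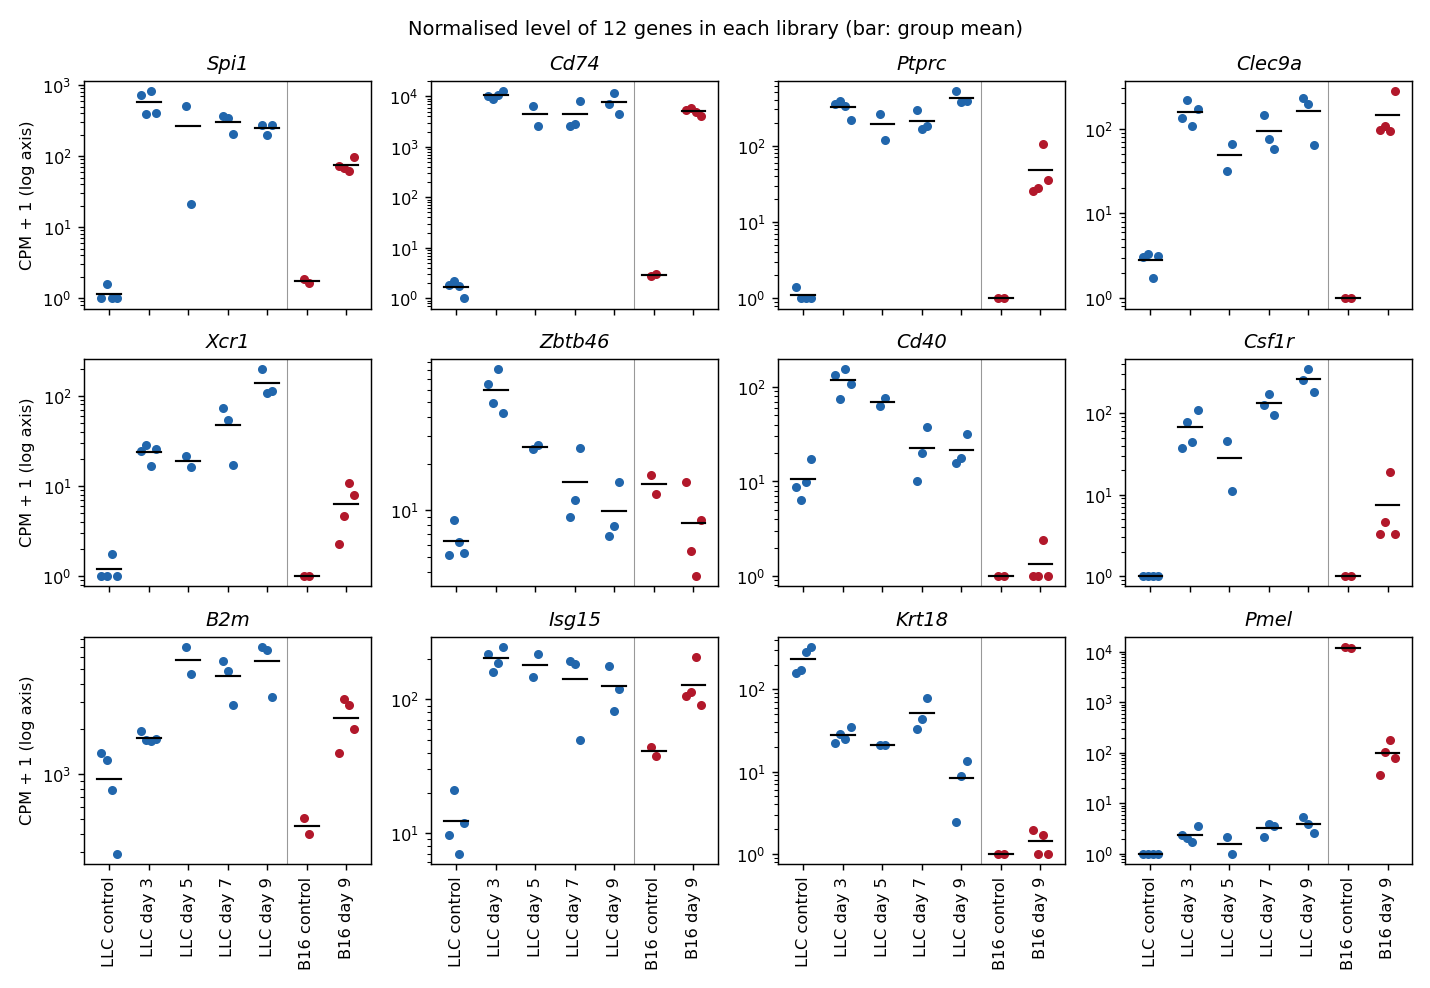
Levels of 12 genes in each library (CPM + 1, log axis, bar = group mean). Clec9a was 1.83 ± 0.734 CPM (SD, n = 4) in LLC controls and 162 ± 87.0 (n = 3) at day 9; Pmel was 12086 ± 474 (n = 2) in B16 controls and 98.9 ± 60.0 (n = 4) at day 9.

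What had changed by day 3 in LLC cells that became CD45+ MHC-II+? Messenger RNA of class II genes was almost absent in the controls and abundant in the cells sorted for MHC-II. Cd74 (ENSMUSG00000024610, chromosome 18: 60803848-60812652), the invariant chain that guides class II molecules, went from 0.687 ± 0.495 to 10615 ± 1511 CPM (log2 13.63 ± 0.70, n = 4 against 4, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.83e-12). H2-Aa (ENSMUSG00000036594, chromosome 17: 34282744-34287823) had no counts in the controls and rose at least 1598-fold (adjusted p = 1.92e-08). Ciita, the master regulator of class II transcription, rose with a ratio of 732 (95% interval 202 to 6046). Of the cDC1 genes, Clec9a (ENSMUSG00000046080, chromosome 6: 129408862-129424763), a receptor for dead cells, rose by 6.34 ± 0.59 (adjusted p = 2.35e-08). Tlr3, the sensor of double-stranded RNA, rose by 6.46 ± 0.83 (adjusted p = 1.82e-06; 5.84 without LLC control 1 and 7.83 without control 4). Wdfy4, needed for cross-presentation, rose by 3.76 ± 0.57 (adjusted p = 2.20e-05). Zbtb46 (ENSMUSG00000027583, chromosome 2: 181387762-181459426), a transcription factor of classical dendritic cells, rose by 3.43 ± 0.46 (adjusted p = 3.34e-06). Xcr1 (ENSMUSG00000060509, chromosome 9: 123852315-123862029), the chemokine receptor that marks cDC1, went from 1 count to 22.7 ± 5.03 CPM (ratio 145, 95% interval 25.8 to 5729, adjusted p = 1.67e-06). Flt3, the growth factor receptor of dendritic cell precursors, stayed near the counting floor with 7 counts over the 4 day 3 libraries, and Ccr7, which guides mature dendritic cells to lymph nodes, had 5.

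Among the genes with the largest fitted rise at day 3, Mpeg1 (perforin-2, a pore-forming protein of phagocytes) rose at least 1254-fold from controls without counts. Ctss (cathepsin S, which trims the invariant chain) rose at least 1068-fold and Pld4 (an endolysosomal exonuclease) at least 653-fold. Ifi205 rose at least 1049-fold, but the gene has close paralogs, so the assignment is uncertain. The largest falls included Aqp5, a water channel of lung epithelium (−5.12 ± 0.84, adjusted p = 8.30e-05), and Ccn5, a matricellular protein (−4.88 ± 0.62, adjusted p = 3.98e-06). Mmp3, a matrix protease (−4.76 ± 0.81, adjusted p = 0.000123), and Krt18, an epithelial keratin (−3.14 ± 0.41, adjusted p = 2.99e-06), also fell. Cd40 (ENSMUSG00000017652, chromosome 2: 165055627-165072948), a costimulatory receptor, rose by 3.66 ± 0.47 (adjusted p = 2.34e-06). The interferon-induced gene Isg15 rose by 4.14 ± 0.46 (adjusted p = 2.38e-07). In the class I pathway the peptide pump Tap1 rose by 2.56 ± 0.39 (adjusted p = 2.05e-05) and the immunoproteasome subunit Psmb9 by 2.28 ± 0.54 (adjusted p = 0.00192). The class I transactivator Nlrc5 rose by 3.14 ± 0.54 (adjusted p = 9.36e-05), with 0 CPM in LLC control 4 against 11.2 to 17.3 in the other controls. The light chain B2m (ENSMUSG00000060802, chromosome 2: 122147686-122153083) did not pass (0.92 ± 0.41, adjusted p = 0.0778). It passed without LLC control 1 (adjusted p = 0.0433), by DESeq2 (0.0478) and voom (0.0316), without the low-count filter (0.0354) and with the replicate number as a block (0.0297, range over the alternatives 0.0297 to 0.722). The proliferation marker Mki67 (0.43 ± 0.78, adjusted p = 0.696) and the cell cycle inhibitor Cdkn1a (0.38 ± 0.44, adjusted p = 0.529) did not pass, although Cdkn1a did by voom (adjusted p = 0.00183, range over the alternatives 0.00183 to 1.00). In all, 2155 genes rose and 2146 fell of 11418 tested. Leaving out 1 library gave 3368 to 3999 changed genes, and testing against a log2 fold change of 1 left 1584.

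Gene lists fixed beforehand were tested with camera on the edgeR fit, with a preset correlation between genes of 0.01, and adjusted over the 27 lists with at least 5 tested members. At day 3, 14 lists rose and 7 fell, and 10 moved with a correlation estimated from the data. The type I interferon list rose with 34 of 36 tested members (35 adjusted over the list alone, adjusted p = 7.26e-34). The cDC1 list, with 30 genes listed, rose with 21 of 22 tested (22 alone, adjusted p = 9.75e-19). Of 14 class II genes listed, all 10 tested rose (10 alone, adjusted p = 1.41e-21). Genes without counts in controls passed the low-count filter only through other groups, so shares of risen members lean upward in such lists. The lists held 34 pan-leukocyte, 28 macrophage and monocyte, 17 cDC2 and 17 pDC genes, and shares here and below are of tested members. Costimulation and maturation rose with 13 of 15 members (13 alone, adjusted p = 1.05e-07) and cross-presentation with 10 of 19 (10 alone, adjusted p = 4.71e-05). Toll-like receptors rose with 10 of 17 (10 alone, adjusted p = 9.83e-06) and the pan-leukocyte list with 27 of 31 (28 alone, adjusted p = 1.41e-21). The class I list rose with 15 of 23 members (16 alone, adjusted p = 1.08e-05), which did not pass with an estimated correlation (adjusted p = 0.0729 with an estimated correlation, range over the alternatives 3.92e-06 to 0.0729). The same holds for interferon gamma genes (15 of 20 rose, 16 alone, adjusted p = 9.96e-10, 0.0523 with an estimated correlation, range 3.53e-13 to 0.0523). It also holds for chemokines and cytokines (15 of 25 rose, 15 alone, adjusted p = 7.63e-07, 0.0504 with an estimated correlation, range 1.09e-07 to 0.0504).

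Markers of other blood cells also rose at day 3. Macrophage and monocyte genes rose with 15 of 20 members (15 alone, adjusted p = 7.37e-13). Among them were Csf1r (ENSMUSG00000024621, chromosome 18: 61100598-61132149), the receptor for macrophage growth factor, at least 132-fold, the chemokine receptor Ccr2 (ratio 1196, 95% interval 214 to 47254) and the lysozyme gene Lyz2 (ratio 1373, 95% interval 380 to 11337). In the cDC2 list 6 of 10 members rose and 1 fell (7 and 1 alone, adjusted p = 2.45e-05), with the lectin genes Mgl2 (at least 640-fold) and Clec12a (at least 120-fold) up. The pDC list rose with 3 of 7 members (3 alone, adjusted p = 0.0209, 0.0523 with an estimated correlation, range over the alternatives 1.24e-06 to 0.0523). Too few members of the other blood lists were tested for a list test: 2 of 3 B cell genes rose, 1 of 2 T and NK cell genes fell, and 1 of 2 neutrophil and mast cell genes rose.

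Lists of the epithelial programme and of housekeeping functions were tested as well. The epithelial list fell with 3 of 7 members, Krt18 among them (3 alone, adjusted p = 0.0118). Oxidative phosphorylation genes fell with 18 of 36 members (21 alone, adjusted p = 9.83e-06), but not with an estimated correlation (adjusted p = 0.302 with an estimated correlation, range over the alternatives 7.69e-07 to 0.302). LLC control 4 stands apart in this list, at 8.30 mean log2 CPM against 7.15 to 7.31 in the other 3 controls, and without it the adjusted p is 0.000361. Genes of DNA replication fell with 14 of 34 members (15 alone, adjusted p = 0.00109, 0.573 with an estimated correlation, range 0.000185 to 0.573). Mitotic genes fell with 10 of 33 (10 alone, adjusted p = 0.00240, 0.601 with an estimated correlation, range 0.000440 to 0.601) and ribosomal protein genes fell with 6 of 35 (0 alone, adjusted p = 0.000692, 0.573 with an estimated correlation, range 2.69e-05 to 0.573). Lysosomal genes rose with 18 of 30 members and fell with 2 (18 and 2 alone, adjusted p = 0.000114, 0.247 with an estimated correlation, range 1.93e-05 to 0.247). Lists that did not move were melanocyte (4 rose, 1 fell of 24, adjusted p = 0.811), p53 targets (3 rose, 2 fell of 22, adjusted p = 0.572), and cholesterol synthesis (2 rose, 3 fell of 24, adjusted p = 0.156). Cholesterol synthesis did pass without LLC control 1 (0.0297) or control 2 (0.0350, range over the alternatives 0.0297 to 0.753). Other lists that did not move were unfolded protein and integrated stress (5 of 26 rose, adjusted p = 0.292), immediate early and dissociation stress (10 rose, 2 fell of 23, adjusted p = 0.186) and mitochondrially encoded genes (0 of 7, adjusted p = 0.989).

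Day 5 shows sorted LLC cells at a point 2 days later, from 2 libraries of unequal quality. The labels do not say whether the days share a culture. Cd74 was up by log2 12.38 ± 0.69 (n = 2 against 4; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.39e-11; 11.48 without day 5 library 1), H2-Aa at least 574-fold and Clec9a by 4.50 ± 0.68 (adjusted p = 3.46e-05). B2m now passed, at 5792 CPM over 2 libraries against 925 ± 494 CPM in the controls (2.65 ± 0.47, adjusted p = 0.000239). Cd40 was up by 2.86 ± 0.54 (adjusted p = 0.000481). The gene count was 1615 risen and 927 fallen. Day 5 library 2 had 266764 counts against 2975697 in library 1, and all 443 Batf3 counts of the day lie in library 1. Without library 2 there were 1096 risen and 414 fallen genes, and Batf3, which rose by 6.76 ± 0.76 (adjusted p = 5.45e-07), had a log2 change of −3.56 (adjusted p = 0.718, range over the alternatives 3.58e-23 to 0.718) without library 1.

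Lists at day 5 followed the early pattern in part. Class II genes (10 of 10 rose, 10 alone, adjusted p = 3.81e-22) and the cDC1 list (16 of 22, 19 alone, adjusted p = 2.17e-13) were up. Type I interferon genes (30 of 36, 31 alone, adjusted p = 2.81e-26), class I genes (17 of 23, 20 alone, adjusted p = 1.34e-10) and macrophage genes (14 of 20, 14 alone, adjusted p = 1.15e-12) were up as well, and all 5 lists passed with an estimated correlation. In all, 15 lists rose and 2 fell, and 9 moved with an estimated correlation. Cholesterol synthesis rose with 8 of 24 members (10 alone, adjusted p = 0.000947), led by Insig1, the sensor that holds back sterol synthesis (4.56 ± 0.59, adjusted p = 3.81e-06; 2.21 without day 5 library 2). The call rests on library 1, with adjusted p = 0.0703 when it is left out and 0.258 with an estimated correlation (range over the alternatives 3.03e-06 to 0.258).

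At day 7 the question is whether cells sorted at this later day also expressed these genes. Cd74 was up by 12.41 ± 0.69 (n = 3 against 4; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.78e-12; 11.66 without day 7 library 3), H2-Aa at least 788-fold, Clec9a by 5.56 ± 0.60 (adjusted p = 2.70e-07) and B2m by 2.27 ± 0.44 (adjusted p = 0.000542). Csf1r rose at least 267-fold, and the monocyte-attracting chemokine gene Ccl8 went from 1 count to 1272 ± 481 CPM (n = 3; ratio 7501, 95% interval 1346 to 296350). Cd40 no longer passed (1.26 ± 0.50, adjusted p = 0.0710; 0.64 without day 7 library 3). It passed without LLC control 4 (adjusted p = 0.0219), without day 7 library 1 (0.0436), without both LLC control 4 and day 5 library 2 (0.0257) and by voom (0.0119, range over the alternatives 0.0119 to 0.529). There were 1477 genes up and 973 down, and without day 7 library 1 the numbers were 1047 and 330, without library 2 1095 and 294. Class II genes (10 of 10 rose, 10 alone, adjusted p = 5.28e-26) and type I interferon genes (33 of 36, 34 alone, adjusted p = 1.01e-40) were up. So were macrophage genes (18 of 20, 18 alone, adjusted p = 1.10e-22), the cDC1 list (17 of 22, 18 alone, adjusted p = 6.21e-14) and lysosomal genes (21 rose and 1 fell of 30, 25 and 1 alone, adjusted p = 1.44e-10). Ribosomal protein genes fell with 34 of 35 members (35 alone, adjusted p = 4.20e-16, 0.133 with an estimated correlation, range over the alternatives 1.53e-23 to 0.133).

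**Figure D2:**
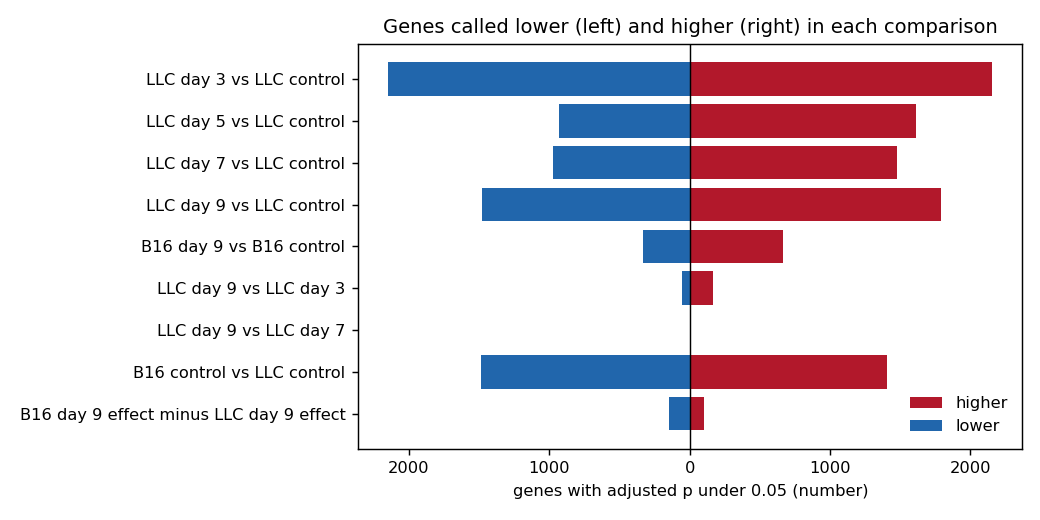
Genes risen and fallen at adjusted p below 0.05 in each contrast, of 11418 tested: 2155 and 2146 at LLC day 3, 1788 and 1482 at LLC day 9, 662 and 335 at B16 day 9. With only the groups compared in the fit, 1675 genes were called at LLC day 9 and 1681 at B16 day 9.

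By day 9, the last day sampled, which genes separated reprogrammed LLC cells from controls? Cd74 stood at 7646 ± 3558 CPM (n = 3; 13.15 ± 0.70, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.79e-12), H2-Aa at least 2047-fold above controls (adjusted p = 1.21e-08) and Ctss at least 6497-fold. Clec9a was up by 6.38 ± 0.61 (adjusted p = 2.64e-08), and Xcr1 reached 138 ± 50.3 CPM (ratio 826, 95% interval 147 to 32716, adjusted p = 5.91e-09). Cadm1, an adhesion molecule of cDC1, rose by 1.36 ± 0.34 (adjusted p = 0.00421). Zbtb46 (0.79 ± 0.54, adjusted p = 0.286) and Cd40 (1.19 ± 0.51, adjusted p = 0.0803) did not pass, although Cd40 did without LLC control 4 (adjusted p = 0.0218), without it and day 5 library 2 (0.0282) and by voom (0.0131, range over the alternatives 0.0131 to 0.498). The class I genes B2m (2.61 ± 0.44, adjusted p = 8.39e-05), Tap1 (2.29 ± 0.41, adjusted p = 0.000153) and Nlrc5 (3.13 ± 0.57, adjusted p = 0.000193) rose. H2-K1 (2.00 ± 0.35, adjusted p = 0.000126) and H2-D1 (2.35 ± 0.47, adjusted p = 0.000532) rose too, but their counts cannot be assigned with certainty among similar heavy chains. LLC control 4 was low in H2-D1 (463 CPM against 2207 to 2452 in the other controls) and in Nlrc5 (0 against 11.2 to 17.3). Genes of macrophages included Csf1r (at least 544-fold, adjusted p = 3.35e-08) and Cybb, the phagocyte oxidase (at least 423-fold). Mrc1, the mannose receptor (at least 157-fold), and Adgre1, which encodes F4/80 (at least 33.6-fold, adjusted p = 6.32e-05), rose as well.

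Genes lower in sorted LLC cells at day 9 than in controls were led by Slc14a1, a urea transporter, with 3 counts (ratio 252 lower, 95% interval 86.1 to 1224). The elastase gene Cela1 was at least 19.4-fold lower and without counts. Krt18 fell to 7.30 ± 5.59 CPM (−4.88 ± 0.54, adjusted p = 2.26e-07; −5.51 without day 9 library 3), although pseudogenes of Krt18 make its assignment uncertain. Of matrix genes, Cthrc1 fell by 5.98 ± 0.59 (adjusted p = 9.50e-08), or by 5.32 without LLC control 4, and the collagen gene Col3a1 by 3.01 ± 0.59 (adjusted p = 0.000705), or by 3.84 without day 9 library 3 (range of adjusted p over the alternatives 5.63e-11 to 0.0162). LLC control 4 stands apart in both, with Cthrc1 at 356 CPM against 102 to 124 and Col3a1 at 329 CPM against 1556 to 1736 in the other controls. In total 1788 genes rose and 1482 fell, and the numbers were 1399 and 731 without day 9 library 1 and 1468 and 904 without library 2.

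Lists at day 9 rose for macrophage genes (18 of 20, 18 alone, adjusted p = 9.38e-28), the pan-leukocyte list (27 of 31, 28 alone, adjusted p = 4.40e-28), type I interferon genes (34 of 36, 35 alone, adjusted p = 5.30e-38), and interferon gamma genes (18 of 20, 18 alone, adjusted p = 9.40e-16). They also rose for class II genes (10 of 10, 10 alone, adjusted p = 1.88e-25), the cDC1 list (18 of 22, 19 alone, adjusted p = 2.75e-17), class I genes (16 of 23, 18 alone, adjusted p = 1.19e-10) and costimulation (11 of 15, 13 alone, adjusted p = 1.27e-07). Lysosomal genes rose with 24 of 30 members and fell with 1 (26 and 2 alone, adjusted p = 2.85e-11), Ctsh, a lysosomal protease, by 6.69 ± 0.47 (adjusted p = 2.44e-10). Ribosomal protein genes fell with 30 of 35 members (34 alone, adjusted p = 1.38e-10, 0.236 with an estimated correlation, range over the alternatives 2.28e-14 to 0.236). Oxidative phosphorylation fell with 19 of 36 (24 alone, adjusted p = 5.82e-07, 0.236 with an estimated correlation, range 3.52e-08 to 0.236). LLC control 4 has the highest oxidative phosphorylation level of the controls, and without it the adjusted p is 3.06e-05. Mesenchymal and matrix genes fell with 10 of 30 members and rose with 2 (12 and 2 alone, adjusted p = 0.00584, 0.278 with an estimated correlation, range 0.000379 to 0.278). In all, 14 lists rose and 6 fell, and 13 moved with an estimated correlation.

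**Figure D3:**
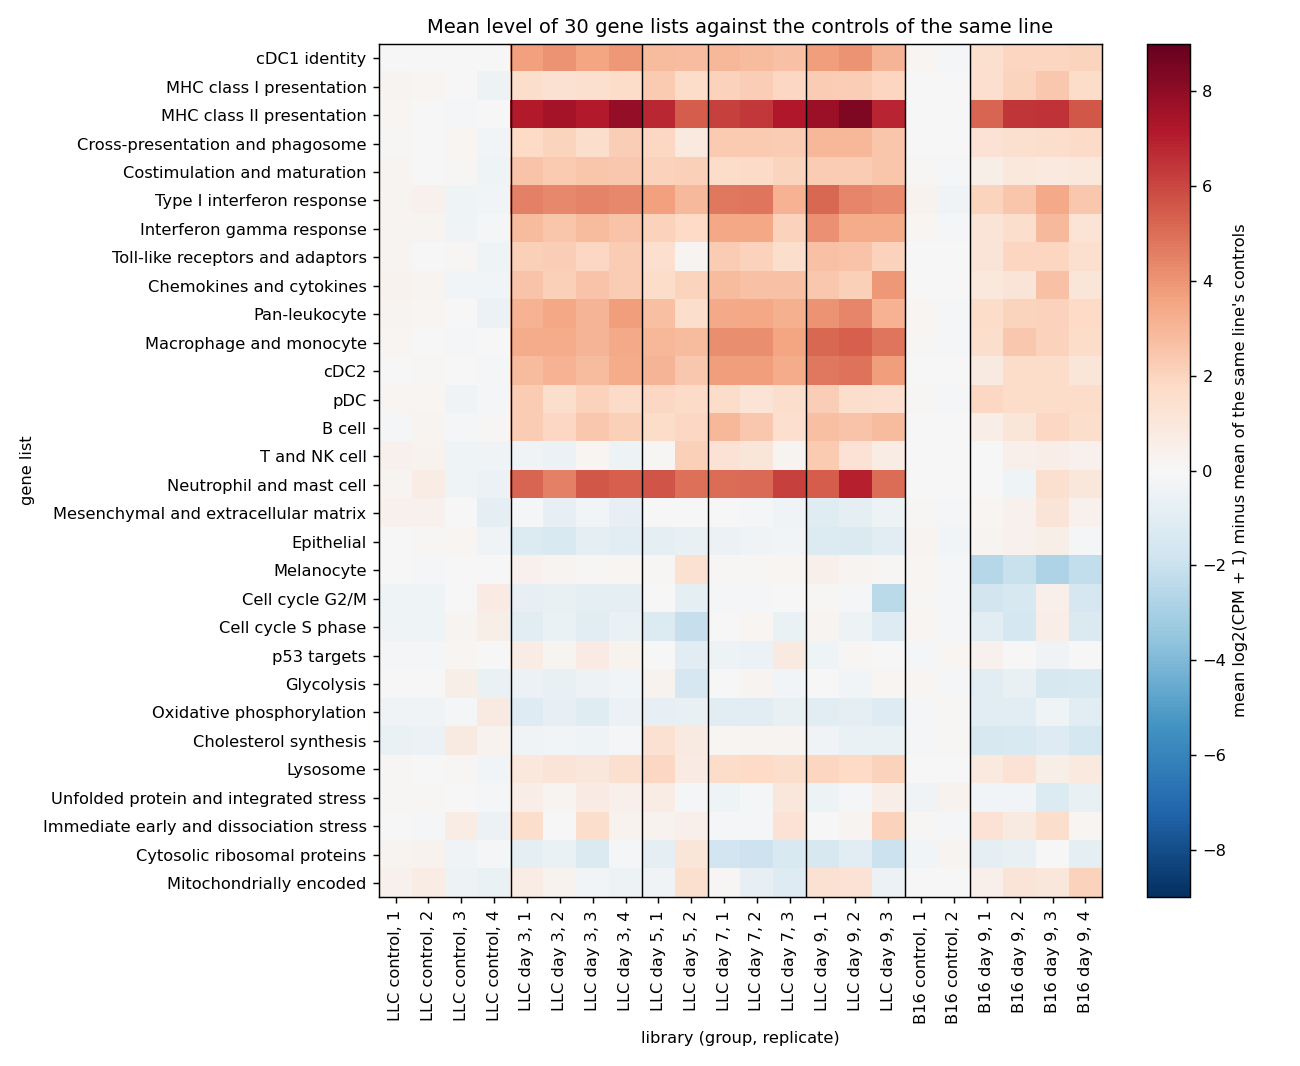
Mean log2 level of each of the 30 gene lists in each library, minus the mean of the same line's controls. By camera 14 lists rose and 6 fell at LLC day 9 (13 of the 20 with an estimated correlation), and 16 rose and 8 fell at B16 day 9 (6 of the 24).

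How did late LLC cells differ from early ones? The comparison of day 9 with day 3 shares no library with the controls. The sample labels give CD45+ MHC-II+ for both days, but the protocol also describes the eGFP+ CD45+ sort at day 9, so a difference of gate is not excluded. C1qb and C1qc, chains of complement C1q made by macrophages, went from 2 and 3 counts at day 3 to 51.6 ± 15.0 and 41.6 ± 10.0 CPM at day 9 (n = 3 against 4; ratios 341, 95% interval 92.7 to 2843, and 201, 67.2 to 986). Fgl2, a secreted regulator of macrophages, rose by 6.43 ± 0.56 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.27e-06) and Mrc1 by 4.36 ± 0.54 (adjusted p = 7.15e-05). The scavenger receptor Cd36 rose by 3.92 ± 0.49 (adjusted p = 4.04e-05), Cybb by 3.90 ± 0.56 (adjusted p = 0.000327) and Sirpa, the receptor for CD47, by 3.39 ± 0.46 (adjusted p = 7.15e-05). Xcr1 rose further, by 2.60 ± 0.48 (adjusted p = 0.00239), while Clec9a (0.04 ± 0.46, adjusted p = 0.996) and Cd74 (−0.47 ± 0.43, adjusted p = 0.758) did not pass. Zbtb46 fell by 2.65 ± 0.50 (adjusted p = 0.00297) and Zfp366, a dendritic cell transcription factor known as DC-SCRIPT, by 4.47 ± 0.72 (adjusted p = 0.00159). The interferon-induced membrane gene Ifitm1 fell by 4.12 ± 0.51 (adjusted p = 2.97e-05) and Cxcl14, a chemokine, was lower with a ratio of 101 (95% interval 28.0 to 838). Cd40 fell by 2.47 ± 0.49 (adjusted p = 0.00552), but not without day 9 library 1 (0.0591) or library 2 (0.0531, range over the alternatives 6.31e-06 to 0.0677). B2m rose by 1.70 ± 0.43 (adjusted p = 0.0390), a call that 6 of the 7 fits with a library left out lost (adjusted p 0.0965 to 0.196, range over the alternatives 9.26e-06 to 0.738).

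In this comparison 168 genes rose and 51 fell, and fits with a library left out called 117 to 158, of which 16 to 31 fell (134, 140 and 127 without day 3 libraries 1, 2 and 3, and 117 and 140 without day 9 libraries 1 and 2). The macrophage list rose with 8 of 20 members (11 alone, adjusted p = 2.12e-21, 0.000993 with an estimated correlation, range over the alternatives 5.72e-22 to 0.000993), cross-presentation genes with 3 of 19 (6 alone, adjusted p = 1.60e-06) and the cDC2 list with 2 of 10 (5 alone, adjusted p = 4.92e-08). Lysosomal genes rose with 3 of 30 members (8 alone, adjusted p = 6.58e-09, 0.171 with an estimated correlation, range 1.06e-10 to 0.171). The cDC1 list (1 rose and 1 fell; adjusted p = 0.478), class II genes (2 rose; adjusted p = 0.125) and type I interferon genes (0; adjusted p = 0.249) did not move. Without day 9 library 3, class II genes (adjusted p = 0.00408, range over the alternatives 0.00408 to 0.807) and type I interferon genes (0.0268, range 0.0268 to 0.858) passed, and class II genes also without day 3 library 4 (0.0476).

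Of the steps between neighbouring days, those with day 5 hang on its 2 libraries. From day 3 to day 5, Insig1 rose by 3.33 ± 0.57 (n = 2 against 4; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00186) and Ccl8 by 3.59 ± 0.67 (adjusted p = 0.00347), and Cxcl14 fell by 4.14 ± 0.74 (adjusted p = 0.00346). Insig1 lost the call without day 5 library 2 (0.99, adjusted p = 0.780), with only the groups compared (0.0554) and by voom (0.171, range over the alternatives 6.02e-09 to 0.780). Ccl8 (0.0950, range 3.18e-10 to 0.0950) and Cxcl14 (0.206, range 2.26e-06 to 0.206) lost it by voom. There 314 genes rose and 62 fell, but 2053 changed without day 5 library 1 and 22 without library 2, and 233, 190, 201 and 177 without day 3 libraries 1 to 4. From day 5 to day 7, Cd36 rose by 4.69 ± 0.79 (adjusted p = 0.00229) and Insig1 fell by 4.32 ± 0.65 (adjusted p = 0.00154). Cd36 lost the call without day 5 library 2 (0.106), with only the groups compared (0.145) and by voom (0.317, range 2.25e-08 to 0.317). Insig1 lost it without day 5 library 2 (−2.01, adjusted p = 0.402) and with only the groups compared (0.193, range 3.10e-12 to 0.402). There 42 genes rose and 240 fell, with 2098 changed without day 5 library 1 and 3 without library 2, and 112 and 57 without day 7 libraries 1 and 2. From day 7 to day 9 no gene passed (n = 3 against 3), with 524 genes at unadjusted p below 0.05 and 4 and 221 genes called by DESeq2 and limma voom. Clec9a (0.82 ± 0.50, adjusted p = 1.00) and Xcr1 (1.57 ± 0.52, adjusted p = 0.906) are examples that did not pass, although Xcr1 did by voom (adjusted p = 0.0312, range over the alternatives 0.0312 to 1.00). By camera 14 of the 27 lists rose in this step and 5 fell, 4 of them also with an estimated correlation and 4 by fry. Those 4 were macrophage genes (0 of 20 rose, 7 alone, adjusted p = 7.33e-16, 0.00448 with an estimated correlation, 0.00199 by fry), the cDC1 list (0 of 22, 5 alone, adjusted p = 2.18e-09, 0.00674 and 0.00580), costimulation (0 of 15, 1 alone, adjusted p = 9.98e-05, 0.00674 and 0.00568) and, lower, the epithelial list (0 of 7, 1 alone, adjusted p = 0.00115, 0.0211 and 0.00216). From day 3 to day 5, 13 lists moved, and from day 5 to day 7, 11 did, 0 of them with an estimated correlation in either step.

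Did the same factors act on B16 melanoma? Sorted B16 cells at day 9 had lower levels of many pigment cell genes and higher levels of class II genes than unsorted controls. Pmel (ENSMUSG00000025359, chromosome 10: 128704195-128720238), the scaffold of the melanosome, fell from 12086 ± 474 to 98.9 ± 60.0 CPM (−6.94 ± 0.54, n = 4 against 2, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.81e-08). The protease gene Bace2 fell by 5.77 ± 0.56 (adjusted p = 6.52e-07) and the channel gene Trpm1 by 5.23 ± 0.77 (adjusted p = 5.78e-05). Mitf (ENSMUSG00000035158, chromosome 6: 97807052-98021349), the master regulator of pigment cells, did not pass (−1.40 ± 0.54, adjusted p = 0.113; −0.68 without B16 control 1). Mitf passed by voom (0.0131), with only the groups compared (0.0216) and without LLC control 4 and day 5 library 2 (0.0252, range over the alternatives 0.0131 to 0.744). Cd74 rose by 11.35 ± 0.89 (adjusted p = 2.76e-08) and, from controls without counts, H2-Aa at least 289-fold, Clec9a at least 116-fold (adjusted p = 4.73e-06), Clec12a at least 75.7-fold, Irf8 at least 120-fold and Ctss at least 302-fold. The largest rises also took in Cd36 (at least 983-fold), the eosinophil-attracting chemokine gene Ccl24 (at least 684-fold) and the transcription factor gene Irf5 (at least 538-fold). Nlrc5 rose by 3.86 ± 0.86 (adjusted p = 0.00527; 0.0944 without control 1 and 0.109 without control 2, range over the alternatives 3.64e-06 to 0.109) and Psmb9 with a ratio of 57.9 (95% interval 15.9 to 480). B2m rose by 2.38 ± 0.56 (adjusted p = 0.00714), a call lost without either B16 control (0.0989 without control 1, 0.156 without control 2, range over the alternatives 1.27e-06 to 0.156). Xcr1 was up at least 3.96-fold at 5.37 ± 3.68 CPM (adjusted p = 0.0226), but not without a B16 control (0.167 and 0.222; range 0.00230 to 0.222). Zbtb46 did not pass (−0.81 ± 0.54, adjusted p = 0.373; −1.46 without B16 day 9 library 1), and Wdfy4, Cd40 and Adgre1 stayed at the counting floor.

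In B16, 662 genes rose and 335 fell, and the numbers were 223 and 66 without control 1 and 150 and 104 without control 2. Fitting only the groups compared called 1681 genes in B16, against 1675 at LLC day 9 in the same setting. Without LLC control 4 and LLC day 5 library 2, 2337 genes were called in B16. The number for B16 thus depends on the LLC libraries in the fit, and the main counts do not rank the responses of the lines. By camera 16 lists rose and 8 fell, 6 of them also with an estimated correlation. The melanocyte list fell with 14 of 24 members (17 alone, adjusted p = 2.14e-20), and class II genes rose with 9 of 10 (9 alone, adjusted p = 5.97e-21). Class I genes rose with 14 of 23 (15 alone, adjusted p = 6.03e-11), the cDC1 list with 10 of 22 (12 alone, adjusted p = 1.58e-06) and macrophage genes with 7 of 20 while 1 fell (9 and 1 alone, adjusted p = 2.70e-06). These 5 lists passed also with an estimated correlation. Type I interferon genes rose with 22 of 36 members (31 alone, adjusted p = 7.76e-20, 0.0562 with an estimated correlation, range over the alternatives 7.06e-24 to 0.0562). Chemokines and cytokines rose with 6 of 25 (8 alone, adjusted p = 0.000796, 0.194 with an estimated correlation, range 1.53e-06 to 0.194). B16 day 9 library 3 stands apart in the chemokine list (3.54 mean log2 CPM against 1.86 to 2.08), in mitotic genes (5.78 against 3.62 to 3.82) and in oxidative phosphorylation (7.82 against 7.16 to 7.20). Without it the chemokine list has an adjusted p of 0.0146. Cholesterol synthesis fell with 8 of 24 members (13 alone, adjusted p = 5.75e-10, 0.0562 with an estimated correlation, range 1.28e-12 to 0.0562). Among its members were Insig1 (−2.70 ± 0.58, adjusted p = 0.00352) and Acat2, which makes a sterol precursor (−2.95 ± 0.66, adjusted p = 0.00541). Immediate early and dissociation stress genes rose with 3 of 23 members (3 alone, adjusted p = 0.00843, 0.432 with an estimated correlation, range 0.000913 to 0.432). Mitochondrially encoded genes rose with 0 of 7 called (0 alone, adjusted p = 0.0349, 0.432 with an estimated correlation, range 0.00662 to 0.432). B16 day 9 library 4 had 4.16% of counts in mitochondrially encoded genes against 1.33 to 2.28% in the other 3, and without it the adjusted p is 0.124. Glycolysis fell with 8 of 22 members (12 alone, adjusted p = 4.58e-07, 0.110 with an estimated correlation, range 5.31e-09 to 0.110).

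Before the factors, how far apart were the lines? B16 controls expressed pigment genes that LLC controls lacked, Pmel at least 25640-fold, Mlana, a melanosome antigen, at least 5154-fold and the tyrosinase gene Tyr at least 1346-fold higher (n = 2 against 4). Mitf was higher by 3.75 ± 0.59 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.21e-05; 3.07 without B16 control 1). Col3a1 was at least 1284-fold and Krt18 at least 188-fold lower in B16, and H2-K1 lower by 2.35 ± 0.45 (adjusted p = 0.000341). In this contrast 1404 genes were higher and 1487 lower in B16, with 907 and 793 called when B16 control 1 was left out, and 916 and 633 without control 2. The melanocyte list was higher with 22 of 24 members (22 alone, adjusted p = 2.41e-43) and the mesenchymal and matrix list lower with 21 of 30 and higher with 3 (23 and 3 alone, adjusted p = 2.43e-10). The epithelial list was lower with 4 of 7 (6 lower and 1 higher alone, adjusted p = 0.000992), and class I genes lower with 10 of 23 and higher with 1 (11 and 1 alone, adjusted p = 0.000556, 0.316 with an estimated correlation, range over the alternatives 8.07e-05 to 0.316).

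Across the 11418 genes the day 9 effects of the lines, which share no library, correlated at Pearson 0.584 (jackknife SE over libraries 0.0946) and Spearman 0.487. Genes are not independent replicates, so no p-value is attached. Of 594 genes called in both lines, 571 (96.1%) changed in the same direction, against 66.4% of all 11418 genes, with 466 risen in both against 103.7 if the calls were independent and 105 fallen against 43.5. Cd74, H2-Aa, Clec9a, Ctss and Tap1 are among those risen in both. In B16, Tap1 (2.31, adjusted p = 0.00639) lost the call without control 1 (0.0989) or control 2 (0.141, range over the alternatives 8.50e-05 to 0.141).

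Which genes responded differently in B16? In the interaction contrast, the day 9 effect in B16 minus that in LLC, the median of all genes was 0.18, which is not subtracted from the values given. Irf7, which amplifies interferon, differed by −4.80 ± 0.83 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00169; −3.62 and adjusted p = 0.105 without B16 control 1, −5.54 without control 2, range over the alternatives 2.89e-09 to 0.105). Oas1a, whose paralogs make its assignment uncertain, differed by −5.02 ± 0.82 (adjusted p = 0.000926; −5.79 without LLC control 2). Psap, the saposin precursor, differed by −3.49 ± 0.65 (adjusted p = 0.00350), going from 409 ± 152 to 9082 ± 3386 CPM in LLC and from 518 ± 108 to 1021 ± 439 in B16. Hexa, a lysosomal hexosaminidase, differed by −2.75 ± 0.51 (adjusted p = 0.00361). The leukocyte actin-bundling gene Lcp1 (−5.65 ± 0.88, adjusted p = 0.000491; −6.40 without LLC control 1 and −4.99 without B16 control 1) and the asparagine protease gene Lgmn (−2.83 ± 0.47, adjusted p = 0.00113) differed too. B2m (−0.23 ± 0.66, adjusted p = 0.945), Tap1 (0.02 ± 0.57) and Cd74 (−1.80 ± 1.03, adjusted p = 0.447) did not differ by the test. In all 105 genes were higher and 150 lower, and without LLC day 9 library 2 the numbers were 57 and 99. There were 12 higher and 49 lower without control 1, and 13 and 83 without control 2.

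Of the lists, 2 were higher and 12 lower in the interaction, and 0 of these 14 moved with an estimated correlation. The type I interferon list was lower with 8 of 36 members (17 alone, adjusted p = 1.67e-15, 0.232 with an estimated correlation, range over the alternatives 1.00e-21 to 0.232), with a median of −1.71 over 28 members counted in all 4 groups. Lysosomal genes were lower with 5 of 30 (8 alone, adjusted p = 9.14e-08, 0.232 with an estimated correlation, range 3.20e-09 to 0.232; median −0.90 over 28). Ribosomal protein genes were higher (median 0.91 over 35; adjusted p = 5.39e-05, 0.615 with an estimated correlation, range 4.01e-08 to 0.615). The cDC1 list (median −0.52 over 10 of 22 tested members, adjusted p = 0.453) and class I genes (median −0.01 over 18 of 23, adjusted p = 0.707) did not pass by camera. This does not show equal responses. Over all tested cDC1 members the list mean went from 2.74 to 6.35 log2 CPM in LLC and from 1.96 to 3.79 in B16.

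**Figure D4:**
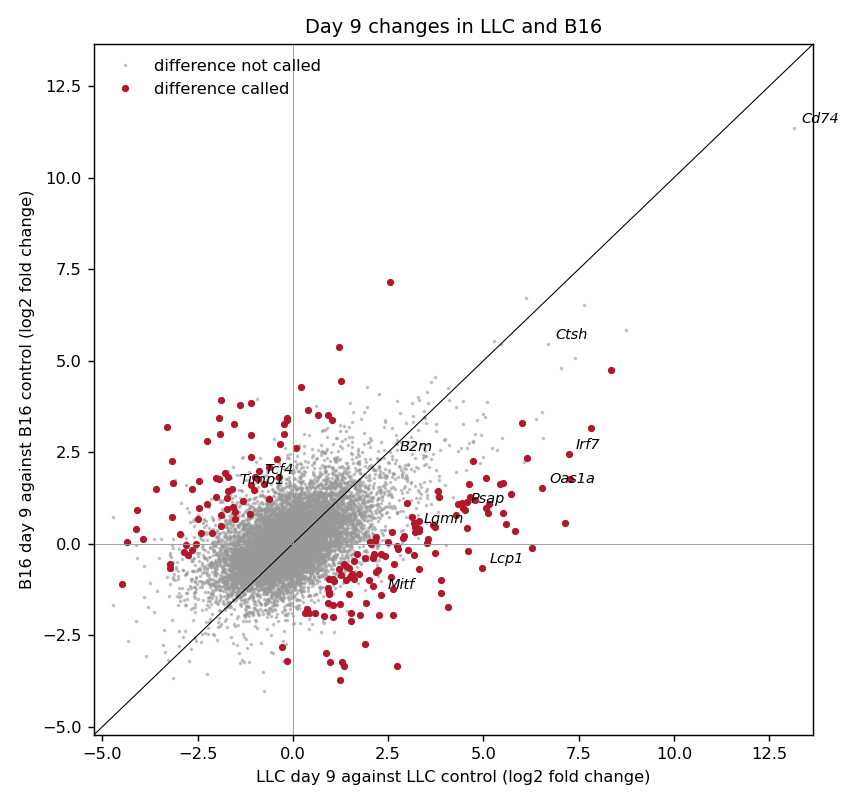
Day 9 log2 fold change against the same line's controls in LLC and B16, for 9811 genes with more than 3 counts in all 4 groups (Pearson 0.524). The difference was called for 196 of them, with a lower day 9 change in B16 than in LLC for 122 and a higher one for 74.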

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

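The tests of low depth and of a wrong label for LLC day 5 replicate 2, of a label swap for LLC control replicate 4, of unreprogrammed cells for B16 day 9 replicate 3, and of other splits for the lists of day 9 against day 7 were chosen only after the results were seen. Within groups of 4 libraries, 310 measures were checked for a library far from the others with Dixon's criterion, and 18 met it. Chance gives about 1 in 20 groups, or 15.5 of these 310, so single cases carry little weight. They were 5 in LLC control replicate 4, 5 in B16 day 9 replicate 3, 4 in B16 day 9 replicate 1, 2 in LLC control replicate 3 and 1 each in LLC control replicate 2 and B16 day 9 replicate 4.

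LLC day 5 replicate 2 detected 16393 genes from 266764 counts. Low depth alone is excluded, since every other library thinned to that total detected at most 11510 genes. An LLC control under a wrong label is excluded by its MHC class II list mean of 6.80 log2 CPM. Among 7230 genes nearly absent elsewhere, its counts rose with transcript length (Spearman 0.337, against −0.047 to 0.059 in the other libraries), so reads from genomic DNA are a candidate explanation. No biological explanation was tested.

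LLC control replicate 4 stood apart from the other LLC controls, with oxidative phosphorylation at 8.30 mean log2 CPM (others 7.15 to 7.31), H2-D1 at 463 CPM (2207 to 2452), Nlrc5 at 0 (11.2 to 17.3), Cthrc1 at 356 (102 to 124) and Col3a1 at 329 (1556 to 1736). Low depth alone is excluded, since the other controls thinned to its total correlated with each other at 0.952 or more while it correlated with them at 0.777 to 0.795. A swap with a B16 library is excluded by its melanocyte list mean of 1.45. Its deviation followed the GC content of transcripts (Spearman −0.464 over 11408 genes, against −0.251, 0.021 and 0.179 in the others), so a GC bias of the library may contribute. No biological explanation was tested.

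B16 day 9 replicate 3 stood apart in chemokines (3.54 mean log2 CPM, others 1.86 to 2.08), mitotic genes (5.78, others 3.62 to 3.82), oxidative phosphorylation (7.82, others 7.16 to 7.20), Rps2 (481 CPM, others 258 to 273) and Irf7 (231 CPM, others 75.9 to 83.6). The chemokine (3.54) and mitotic (5.78) means lie above those of the B16 controls by more than the controls' range. A share of cells like these controls can therefore not alone give either mean. A partial share is not excluded, since there are 2 controls only. Oxidative phosphorylation (7.82) lies between the other day 9 libraries and the B16 controls (mean 8.18). Its deviation showed no strong monotone trend with GC content (Spearman 0.089, others 0.316, −0.013 and −0.327). A GC effect that is not monotone would escape this test, so GC bias is not excluded. No biological explanation was tested.

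Other libraries far from their group were these. B16 day 9 replicate 1 had 2909900 counts against 1065265 to 1316555. Its cDC1 list mean was 3.42 against 3.90 to 3.94 log2 CPM, its pDC list mean 3.10 against 2.92 to 2.93, and its Cadm1 level 300.2 CPM against 505 to 542. LLC control replicate 2 had 16.2% of counts in its top 50 genes against 13.3 to 13.6%. LLC control replicate 3 had Clec9a at 0.745 CPM against 2.06 to 2.35 and Tcf4 at 157 CPM against 280.2 to 289. B16 day 9 replicate 4 had Clec9a at 274 CPM against 92.7 to 107.

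The day 9 effect differed between the lines by the interaction test for 255 genes, with a median over all genes of 0.18. Named genes with a lower effect in B16 than in LLC were Lcp1 (−5.65), Oas1a (−5.02), Irf7 (−4.80), Mitf (−3.71) and Psap (−3.49). The same held for Plpp1 (−2.95), Lgmn (−2.83), Hexa (−2.75) and Sirpa (−2.41). A lower effect is not a lower level, and Mitf did not pass at B16 day 9 against the B16 controls. The effect was higher in B16 for Timp1 (3.08) and Tcf4 (2.69). Leaving out 1 library ended some of these calls. For Sirpa it was 8 of 13 fits (adjusted p 0.0502 to 0.158, range over the alternatives 0.00440 to 0.173): without LLC control 3, LLC day 9 replicate 1 or 3, B16 control 1 or 2, or B16 day 9 replicate 1, 3 or 4. Without B16 control 1 or 2 the call ended for Tcf4 (0.134 and 0.161, range 0.000330 to 0.161) and Timp1 (0.110 and 0.141, range 0.00186 to 0.141). Without B16 control 1 it ended for Mitf (0.119, range 2.64e-05 to 0.119) and Irf7 (0.105, range 2.89e-09 to 0.105). Lists moved in the interaction by camera, with the median over members above 3 counts in all 4 groups and the number of such members, were MHC class II (−2.33, 3 of 10), type I interferon (−1.71, 28 of 36), melanocyte (−1.67, 7 of 24), interferon gamma (−1.32, 11 of 20), pan-leukocyte (−1.29, 12 of 31), costimulation (−1.13, 9 of 15), lysosome (−0.90, 28 of 30), glycolysis (−0.83, 21 of 22), unfolded protein (−0.60, 26 of 26), Toll-like receptors (−0.58, 10 of 17), cholesterol synthesis (−0.46, 24 of 24), cross-presentation (−0.40, 13 of 19), mesenchymal (0.87, 16 of 30) and ribosomal proteins (0.91, 35 of 35). With an estimated correlation 0 of these lists moved (camera), and fry moved 3.

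Other splits of the same libraries were fitted for contrasts with at least 3 libraries per group. For genes, no other split called as many as the real one at LLC day 3 (4301 genes, at most 2 in the other 34 splits, 1 of 35 as many). The same held at day 7 (2450, at most 1351, 1 of 35) and day 9 (3270, at most 1958, 1 of 35). It also held for day 9 against day 3 (219, at most 24, 1 of 35). A share of 1 in 35 is the lowest these splits can give, and the replicates may be technical. The splits that called 1351 and 1958 genes set 3 controls against the 3 reprogrammed libraries and the remaining control, so they hold much of the real contrast. Splits that mixed the groups further called at most 3 genes at day 7 and 448 at day 9. For day 9 against day 7 the 10 splits are too few for a share under 0.05, with 0 genes in the real split and at most 0 in the others (10 of 10 as many), and the same holds for its lists, with 19 in the real split and at most 19 in the others (2 of 10 as many). For lists, no other split gave as many at day 3 (21 lists, at most 20 in the others, 1 of 35). The gap is too narrow to exclude chance, since the real contrast moved 19 lists without day 3 library 2. But day 3 splits that exchanged 1 library per group keep much of the real contrast. Those gave 12 to 20 lists, and those that exchanged 2 gave 0 to 8. Chance is not excluded either at day 7 (15, at most 21, 18 of 35) or day 9 (20, at most 20, 2 of 35), or for day 9 against day 3 (12, at most 21, 16 of 35). Splits of 3 controls against the rest gave 16 to 17 lists at day 7 and 15 to 19 at day 9. Splits that keep part of the real contrast cannot decide whether its lists moved by chance.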

How the results depend on the processing

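The fit without LLC day 5 replicate 2 and LLC control replicate 4 was chosen after seeing the data; the other alternatives were planned. Where a cause is not named below, the cause was not tested. For named genes 13621 of 15055 values kept their direction and side of the threshold, 1276 lost the call, 156 gained it and 2 changed direction. For single lists the numbers were 2617, 232, 53 and 2 of 2904. Counts of genes stayed within 1.5 times the reported count in 109 of 187 cases and counts of lists in 97 of 108. RLE normalization, and leaving out Spi1, Irf8, Batf3 and the mt- genes, each kept all 11 counts of genes within that bound. The correlation of day 9 effects ranged from 0.505 to 0.638 over the 27 cases, against 0.584 in the main fit. Its jackknife SE of 0.0946 comes from the 22 fits with a library left out. Those fits could hardly move beyond that SE, so it is no test of them.

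The 4 values that changed direction rest on 1 library each. The ribosomal protein list at LLC day 5 fell without LLC day 5 replicate 1 (adjusted p = 0.000909; range 1.94e-05 to 0.899 with a library left out and 4.34e-06 to 0.976 over all alternatives), and immediate early genes in LLC day 9 against day 3 without LLC day 9 replicate 3 (adjusted p = 0.00627; range 0.00627 to 0.956). Batf3 at LLC day 5 was −3.56 without LLC day 5 replicate 1 and 7.545 without replicate 2, and Icam1 in the interaction was 0.026 without B16 control replicate 1 and −6.22 without replicate 2.

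Leaving out 1 library at a time gave these ranges of genes called: 3368 to 3999 at LLC day 3, 1510 to 2757 at day 5, 1377 to 2451 at day 7, 2130 to 3272 at day 9, 254 to 1034 at B16 day 9, 117 to 158 for day 9 against day 3, 22 to 2053 for day 5 against day 3, 3 to 2098 for day 7 against day 5, 0 to 0 for day 9 against day 7, 1549 to 3131 between the controls and 61 to 346 in the interaction. Where a group keeps 1 library, it is assumed to vary like the other groups. Lists moved ranged over 19 to 21 at LLC day 3, 16 to 18 at day 5, 15 to 16 at day 7, 17 to 21 at day 9, 21 to 24 at B16 day 9, 11 to 18 for day 9 against day 3, 12 to 15 between the controls and 8 to 16 in the interaction.

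Testing against a log2 fold change of 1, a stricter question, called 1584 genes at LLC day 3, 1087 at day 5, 807 at day 7, 1274 at day 9, 381 at B16 day 9, 82 for day 9 against day 3, 69 for day 5 against day 3, 61 for day 7 against day 5, 1651 between the controls and 95 in the interaction. Voom with sample quality weights called 6673, 730, 4721, 5051, 3554, 1350, 2 and 3 in the first 8 of these contrasts, 221 for day 9 against day 7, 5394 between the controls and 1810 in the interaction. Fitting only the groups compared, which leaves fewer libraries to estimate the spread, called 433 at day 5, 1095 at day 7, 1675 at day 9, 1681 at B16 day 9, 562 for day 9 against day 3, 70 for day 5 against day 3, 0 for day 7 against day 5 (3 by voom, 676 by DESeq2), 1773 between the controls and 138 in the interaction.

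DESeq2 called 337 for day 9 against day 3, 749 for day 5 against day 3, 676 for day 7 against day 5, 4 for day 9 against day 7 and 505 in the interaction. Without the low-count filter the counts were 387, 758, 569, 31 and 446 in the same order, and a minimum count of 50 gave 137 for day 9 against day 3. With LLC day 5 replicate 2 and LLC control replicate 4 left out they were 2337 at B16 day 9, 578 for day 9 against day 3, 129 for day 5 against day 3, 9 for day 7 against day 5, 5 for day 9 against day 7 and 564 in the interaction. With an estimated correlation the lists moved were 10 at LLC day 3, 9 at day 5, 13 at day 9, 6 at B16 day 9, 3 for day 9 against day 3, 4 between the controls and 0 in the interaction, and fry moved 5 for day 9 against day 3 and 3 in the interaction.

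With the replicate number as a block, 547 genes were called at B16 day 9, 174 for day 5 against day 3, 14 for day 7 against day 5, 1876 between the controls and 119 in the interaction. The labels do not say that replicate numbers pair libraries: 11 of 29 pairs with the same number correlated above 0.1 (−0.271 to 0.322), and 7 of 20 libraries correlated best with their own number.

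Counting a gene as detected at 5 counts in place of 1 gave 6731 to 12409 genes per library (median 10400.5). Depth limits what can be said of genes near the floor of 3 counts.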
